A study of Homo sapiens with 10 samples.

How the data were processed

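RNA was measured in U-2 OS cells by poly(A) selection, NEBNext Ultra libraries and single-read sequencing on a NextSeq instrument. Cells had been plated in 6-well plates, dense ones at 10 times the number, synchronized with dexamethasone, kept without serum and given conditioned or control medium for 2 h. The 10 libraries form 4 groups: 3 dense conditioned, 3 dense control, 2 sparse conditioned and 2 sparse control.

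Per the labels, the authors deposited read counts per gene. The submitters' processing notes name STAR for alignment, SAMtools, featureCounts for counting, FastQC and MultiQC for quality and DESeq2 for testing, without versions. The deposited count table holds counts for 58395 genes. A second deposited table holds counts for 29997 of them, 100% of its values equal to the first. A further deposited table gives the authors' DESeq2 results: a signal (mean count over size factors), log2 fold changes with standard errors, a score (the Wald statistic, log2 fold change over its error), and p-values, without naming the contrast. Its log2 fold changes were matched by DESeq2 with a density and a medium term over the 10 libraries (r = 1.00 with the deposited log2 fold changes over 14180 genes, median absolute difference 1.7e-08).

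Counts were used as deposited. The kit is not stated to mark strand. Gene positions are those of GRCh38, gene types those of GENCODE release 29, found for 58275 identifiers, and 57754 identifiers had a current symbol. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Genes were kept by edgeR's filterByExpr by group, which left 22475, and libraries were scaled by TMM (factors 0.952 to 1.07). A quasi-likelihood negative binomial model (robust) was fitted to the 4 groups over all 10 libraries, with no replicate term, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The biological coefficient of variation was 11.8%. Median log2 fold changes over all genes shifted by at most 0.0137 between TMM and RLE scaling.

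Between 51522670 and 81124582 reads per library fell in genes, with 19721 to 21500 genes at 10 or more reads. A floor of 3 reads per library equals 0.0445 CPM in dense control and 0.0486 CPM in sparse control. Bounds against this floor cover counting error only. Chi-square per degree of freedom between replicates was 7.10 to 38.6, so no 2 libraries differ by counting error alone.

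The 6 comparisons were conditioned against control medium in dense and in sparse cultures, the mean and the difference of those effects, and sparse against dense cultures in each medium. In all, 27 gene lists were used, of which 411 of 412 genes matched. Lists with at least 5 tested members (26) were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists. The lists are core clock, TGF-beta and SMAD target, TGF-beta family, BMP and ID target, immediate early, ERK feedback, CREB target, YAP and TAZ target, SRF and MRTF target, NF-kB and cytokine, glucocorticoid receptor target, extracellular matrix, G2 and M phase, S phase, cholesterol, hypoxia and glycolysis, ATF4 and unfolded protein response, p53 target, interferon-stimulated, Notch target, osteoblast lineage, heat shock, mitochondrially encoded, histone, epithelial, leukocyte and endothelial genes. Genes named in the text follow a rule: for each comparison, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 1, the same direction in every same-numbered pair and an approved symbol; up to 3 members of each list with the smallest adjusted p; and members of a fixed set of 10 genes that includes PER1, PER2, BMAL1, NR1D1, DBP, SMAD7, FOS, EGR1 and CCN2. Genes named in 1 comparison were also followed in others. Groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined.

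Alternatives were RLE scaling, no low-count filter, a filter at a mean of 1 CPM, DESeq2's Wald test, limma-voom, replicate number as a block, a fit of the compared groups alone, leaving out each library in turn, leaving out mitochondrially encoded genes, camera with an estimated correlation, and limma's fry. Where leaving out a library leaves a group with 1 library, that library is assumed to vary like the other groups. Whether replicate numbers pair libraries was checked by correlating deviations from group means. Same-numbered dense conditioned and control libraries had r of 0.20, 0.17 and 0.37, sparse ones 0.42, so numbers pair the dense libraries by this check, while 2 pairs are too few to tell in sparse cultures. The main model has no replicate term, and the block is an alternative. The pipeline was tested on simulated data with 200 genes changed. At log2 changes of 0.5 and 1 it recovered 63% and 90% of them in the dense comparison, 43% and 84% in the sparse, 78% and 96% in the averaged, 11% and 82% in the difference, 49% and 88% for density in control medium and 43% and 90% in conditioned medium, with 6 to 14 false calls. Of 26 lists only the raised one was called, but correlated lists were not tested. Circadian series were not analysed: each group has 1 time point.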

Results

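The series measured polyadenylated RNA in U-2 OS cells, a human osteosarcoma line that keeps a circadian clock in culture. Its title names coupling between peripheral circadian oscillators through TGF-beta, a secreted growth factor that signals through SMAD proteins. Dense cultures were plated with 10 times as many cells as sparse cultures. All were synchronized with 1 µM dexamethasone, a glucocorticoid that resets cellular clocks, and kept in serum-free medium for 16 to 18 h. They then received a 2 h pulse of medium conditioned by U-2 OS cells or of control medium. The 10 libraries fall into 4 groups: dense conditioned (n = 3), dense control (n = 3), sparse conditioned (n = 2) and sparse control (n = 2). The sparse groups carry the replicate numbers 1 and 3. Reads assigned to genes came to 63252832, 51522670 and 65368074 in dense conditioned libraries 1, 2 and 3, and to 58969586, 81124582 and 58497722 in dense control. They came to 60028307 and 67432275 in sparse conditioned libraries 1 and 3, and to 56443735 and 65542410 in sparse control. Mitochondrially encoded genes took 2.55% to 3.98% of these reads, and the 10 most abundant genes 3.51% to 4.45%.

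Density and medium separated the libraries more than replicate number did. The first principal component of scaled log2 counts (log2 CPM) over 12241 genes held 60.5% of the variance and parted dense from sparse libraries. The second held 30.1% and parted conditioned from control medium at both densities. Log2 CPM correlated across genes between replicates of a group with r from 0.986 to 0.995, and genes are not independent replicates.

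**Figure D1:**
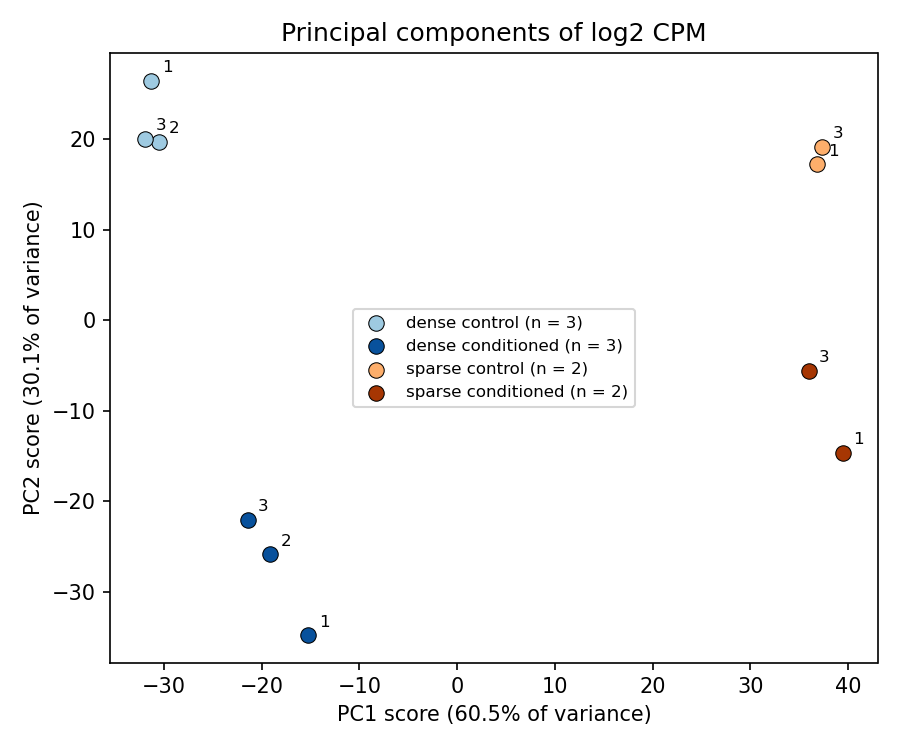
Scores of the 10 libraries on the first 2 principal components of log2 CPM, labelled by replicate number. Dense and sparse libraries lie apart on the first axis (60.5% of the variance), and conditioned and control libraries on the second (30.1%).

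The first comparison asked what conditioned medium changed in dense cultures. Levels are mean CPM ± SD, with n = 3 in each dense and n = 2 in each sparse group, and log2 fold changes are given ± SE with the adjusted p of edgeR's quasi-likelihood test. Genes of the circadian clock moved both ways. PER2, a repressor of the clock feedback loop, rose from 6.27 ± 1.45 to 15.1 ± 2.66 CPM (1.26 ± 0.18, adjusted p = 0.000299). BHLHE40, another repressor in the loop, rose from 210.1 ± 24.4 to 458 ± 70.1 CPM (1.12 ± 0.10, adjusted p = 2.73e-06). NR1D1, the nuclear receptor REV-ERB alpha, which represses BMAL1, fell from 27.0 ± 1.37 to 9.06 ± 2.38 CPM (-1.58 ± 0.15, adjusted p = 2.96e-06). DBP, a clock-driven transcription factor, fell from 11.1 ± 2.89 to 3.16 ± 0.585 CPM (-1.81 ± 0.22, adjusted p = 3.68e-05). PER1 (-0.36 ± 0.18, adjusted p = 0.2) and BMAL1 (-0.18 ± 0.15, adjusted p = 0.474), the positive factor of the loop, did not pass the test. PER1 passed it without the low-count filter (adjusted p = 0.00383) and without dense conditioned 3 (0.0384), in a range over the alternatives of 0.00383 to 0.562. Of the 20 core clock genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), with a median log2 fold change of 0.00, a mean of -0.08 and limma's camera test, which compares a list with the other genes, pointing up (camera adjusted p = 0.963). In genome build GRCh38 these genes lie as follows: PER2 (ENSG00000132326, chromosome 2, 238244038 to 238290102), NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725), DBP (ENSG00000105516, chromosome 19, 48630030 to 48637438) and BHLHE40 (ENSG00000134107, chromosome 3, 4979116 to 4985323).

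Targets of TGF-beta and SMAD signalling rose in dense cultures. SMAD7, the inhibitory SMAD, rose from 32.8 ± 4.42 to 50.4 ± 6.60 CPM (0.62 ± 0.10, adjusted p = 0.000481). SKIL, a SMAD corepressor, rose from 166 ± 15.3 to 446 ± 50.8 CPM (1.42 ± 0.09, adjusted p = 5.28e-08). PMEPA1, a feedback inhibitor of the pathway, rose from 785 ± 78.3 to 1360.4 ± 42.3 CPM (0.79 ± 0.08, adjusted p = 2.73e-06). JUNB, an AP-1 subunit, rose from 68.4 ± 6.91 to 313 ± 33.0 CPM (2.19 ± 0.09, adjusted p = 5.36e-10). CCN2, the connective tissue growth factor gene, was at 165 ± 30.3 CPM in control and 196 ± 55.7 CPM in conditioned medium (0.24 ± 0.22, adjusted p = 0.536). Of 22 list members, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.000115, adjusted p = 0.38 with an estimated correlation). Among TGF-beta family ligands, receptors and SMADs, 6 rose and 5 fell of 20 (7 and 5, camera adjusted p = 0.949). FSTL3, which binds activin, rose (0.57 ± 0.08, adjusted p = 0.000133), and the activin receptor gene ACVR2B fell (-0.85 ± 0.10, adjusted p = 2.32e-05). BMP4, a ligand of the related BMP pathway, fell from 107 ± 11.8 to 20.8 ± 7.46 CPM (-2.36 ± 0.23, adjusted p = 0.000177). Targets of that pathway fell too, with 5 of 9 lower and 0 higher (5 and 1), among them ID2 (-1.79 ± 0.17, adjusted p = 2.19e-06), SMAD6 (-1.13 ± 0.13, adjusted p = 1.72e-05) and ATOH8 (-0.98 ± 0.18, adjusted p = 0.000887), although the list as a whole did not pass camera (adjusted p = 0.116). SMAD6 is a member of both target lists and one of the 2 TGF-beta list members that fell. In GRCh38, SMAD7 (ENSG00000101665, chromosome 18, 48919853 to 48950711), SKIL (ENSG00000136603, chromosome 3, 170357678 to 170396835) and JUNB (ENSG00000171223, chromosome 19, 12791496 to 12793315) are protein-coding genes.

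Inflammatory genes were among the largest rises. CXCL8, the gene of the chemokine interleukin-8, rose from 1.13 ± 0.479 to 1589 ± 1006 CPM (10.44 ± 1.09, adjusted p = 0.00101). PTX3, a secreted pattern recognition protein, rose from 2.62 ± 0.175 to 454 ± 333 CPM (7.44 ± 0.93, adjusted p = 0.00218). CXCL3, another chemokine gene, rose from 0.691 ± 0.266 to 168 ± 131 CPM (7.98 ± 1.16, adjusted p = 0.00431). CXCL10 rose from 6 reads in the 3 control libraries together to 13.8 ± 8.03 CPM (8.80 ± 0.85, adjusted p = 0.000269). VCAM1, an adhesion molecule, had no read in dense control and 7.70 ± 6.30 CPM in conditioned medium, at least 173-fold higher against a floor of 3 reads per library, and its call (adjusted p = 0.022, range 4.06e-13 to 0.198) ended without dense conditioned 2 (0.061), dense control 1 (0.0507), sparse control 1 (0.0689), sparse control 3 (0.0689), by limma-voom (0.198), with numbers 1 and 3 alone (0.111) and without the low-count filter (0.0525). RELB and NFKB2, which encode NF-kB subunits, rose (2.78 ± 0.15, adjusted p = 2.02e-07 and 2.10 ± 0.13, adjusted p = 1.98e-07), as did the cytokine gene LIF (1.90 ± 0.12, adjusted p = 1.72e-07). Of 18 NF-kB and cytokine genes, 17 rose (18 adjusted over the list alone), with a median log2 fold change of 4.46 and of 4.20 with CXCL1 and CXCL2, at 0 reads in dense control, at their bounds of at least 24.1-fold and 17.6-fold (camera adjusted p = 1.43e-20, adjusted p = 0.276 with an estimated correlation). Immediate early genes rose in 19 of 26 cases and fell in 3 (20 and 3, camera adjusted p = 8.6e-10, adjusted p = 0.264 with an estimated correlation). EGR2 rose from 4.87 ± 0.397 to 61.2 ± 6.66 CPM (3.66 ± 0.13, adjusted p = 1.34e-10). EGR1 rose from 48.7 ± 4.79 to 174 ± 9.54 CPM (1.84 ± 0.13, adjusted p = 5.7e-07). ATF3 rose from 9.02 ± 0.992 to 35.0 ± 7.06 CPM (1.96 ± 0.13, adjusted p = 2.01e-07). All 3 encode transcription factors, and FOSL1 rose as well (2.37 ± 0.15, adjusted p = 7.53e-07). FOS was only slightly higher (0.37 ± 0.12, adjusted p = 0.0326, range 0.0111 to 0.117), and its call ended without dense conditioned 2 (0.117), dense conditioned 3 (0.0757), dense control 1 (0.102), dense control 3 (0.113), sparse control 1 (0.0525), sparse control 3 (0.0523), in a fit of the compared groups alone (0.0564) and without the low-count filter (0.0509). The call of CXCL3 ended by limma-voom (0.0653) and with numbers 1 and 3 alone (0.0567) (range 3.7e-24 to 0.0653), and that of CXCL10 by limma-voom (0.0537) (range 1.15e-18 to 0.0537). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) and other chemokine genes have paralogs, so their levels are uncertain if copies shared reads. EGR2 lies at ENSG00000122877, chromosome 10, 62811996 to 62919900, and NFKB2 at ENSG00000077150, chromosome 10, 102394110 to 102402529.

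Mitotic genes fell by small amounts in dense cultures. CENPF (-0.49 ± 0.07, adjusted p = 0.000179), KIF20A (-0.43 ± 0.08, adjusted p = 0.00122) and PLK1 (-0.39 ± 0.08, adjusted p = 0.00214) were among 10 of 17 G2 and M phase genes that fell (11 adjusted over the list alone, camera adjusted p = 0.000499, adjusted p = 0.58 with an estimated correlation). The chaperone genes DNAJB1 (1.36 ± 0.09, adjusted p = 9.75e-08), BAG3 (0.75 ± 0.10, adjusted p = 8.51e-05) and HSPA8 (0.42 ± 0.09, adjusted p = 0.00309) were among 6 of 10 heat shock genes that rose (6 adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.605 with an estimated correlation). HSPA1A and HSPA1B in that list are near-identical copies, so their counts are uncertain. Among markers of epithelial cells, ELF3 (4.91 ± 0.54, adjusted p = 1.88e-05), CLDN4 (0.78 ± 0.13, adjusted p = 0.000537) and KRT18 (0.44 ± 0.09, adjusted p = 0.00162) rose, 3 of 10 (3 adjusted over the list alone, camera adjusted p = 0.0246, adjusted p = 0.276 with an estimated correlation). That list lost its call with the stricter filter (0.23) and with numbers 1 and 3 alone (0.0662). TXNIP, a thioredoxin-binding protein, fell from 49.0 ± 5.72 to 6.20 ± 2.03 CPM (-2.98 ± 0.22, adjusted p = 6.35e-06). So did PDK4, which restrains pyruvate oxidation (-2.73 ± 0.20, adjusted p = 2.72e-07), and HAS2, a hyaluronan synthase (-2.59 ± 0.30, adjusted p = 0.0003).

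The other lists did not pass camera in dense cultures. The counts that follow are genes that rose and fell, then in brackets the same counts adjusted over the list alone and the camera adjusted p. Signalling lists gave 4 and 2 of 13 ERK pathway feedback genes (4 and 2, 0.152), 7 and 4 of 15 CREB target genes (8 and 5, 0.346), 6 and 4 of 20 YAP and TAZ target genes (6 and 5, 0.756), 3 and 0 of 16 SRF and MRTF cytoskeletal target genes (3 and 0, 0.194), 4 and 4 of 14 glucocorticoid receptor target genes (4 and 4, 0.994) and 1 and 2 of 5 Notch target genes (1 and 2, 0.963). Stress and metabolism lists gave 4 and 4 of 16 ATF4 and unfolded protein response genes (4 and 6, 0.963), 4 and 4 of 13 p53 target genes (4 and 4, 0.963), 3 and 3 of 17 hypoxia and glycolysis genes (3 and 4, 0.963), 2 and 1 of 17 cholesterol synthesis and uptake genes (2 and 1, 0.564) and 4 and 1 of 14 interferon-stimulated genes (4 and 1, 0.756). Growth and matrix lists gave 0 and 3 of 17 S phase genes (0 and 3, 0.11), 0 and 0 of 9 replication-dependent histone genes (0 and 0, 0.622), 1 and 0 of 19 extracellular matrix genes (1 and 0, 0.116), 1 and 0 of 8 osteoblast lineage genes (1 and 0, 0.571) and 0 and 0 of 13 mitochondrially encoded mRNAs (0 and 0, 0.232). Markers of another cell type gave 0 and 0 of 7 endothelial cell markers (0 and 0, 0.963). Of 3 leukocyte markers measured, too few for a test, 1 rose and 0 fell, namely CD14, which had 8 reads in dense control and whose call (adjusted p = 0.0436, range 0.0196 to 0.208) ended without dense conditioned 2 (0.208), dense conditioned 3 (0.0543), dense control 1 (0.118), dense control 3 (0.127), sparse conditioned 1 (0.0592), sparse conditioned 3 (0.0551), sparse control 1 (0.0596), sparse control 3 (0.0549), by limma-voom (0.0609) and with numbers 1 and 3 alone (0.117). Median, mean and camera differed in sign for the YAP and TAZ list (median -0.05, mean 0.21), the glucocorticoid receptor list (-0.14 and 0.11), the ATF4 list (-0.05 and 0.10), the p53 list (-0.04 and 0.11), the interferon list (-0.10 and 0.01) and the Notch list, whose median (0.07) and mean (0.05) were above 0 with camera pointing down.

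In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4488 of 22475 genes in dense cultures, 2498 higher and 1990 lower, and 4481 of them moved the same way in all 3 same-numbered pairs. The count was 2825 with numbers 1 and 3 alone. Changes of at least 2-fold were found for 581 genes that rose and 390 that fell. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that replicates are separate cultures. Of the 84 rule-named genes past the threshold in this comparison, 10 lost their call on leaving out a library and 14 under some other alternative. The kit is not stated to mark strand, so overlapping and antisense genes, such as NR1D1 and THRA, cannot be told apart.

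**Figure D2:**
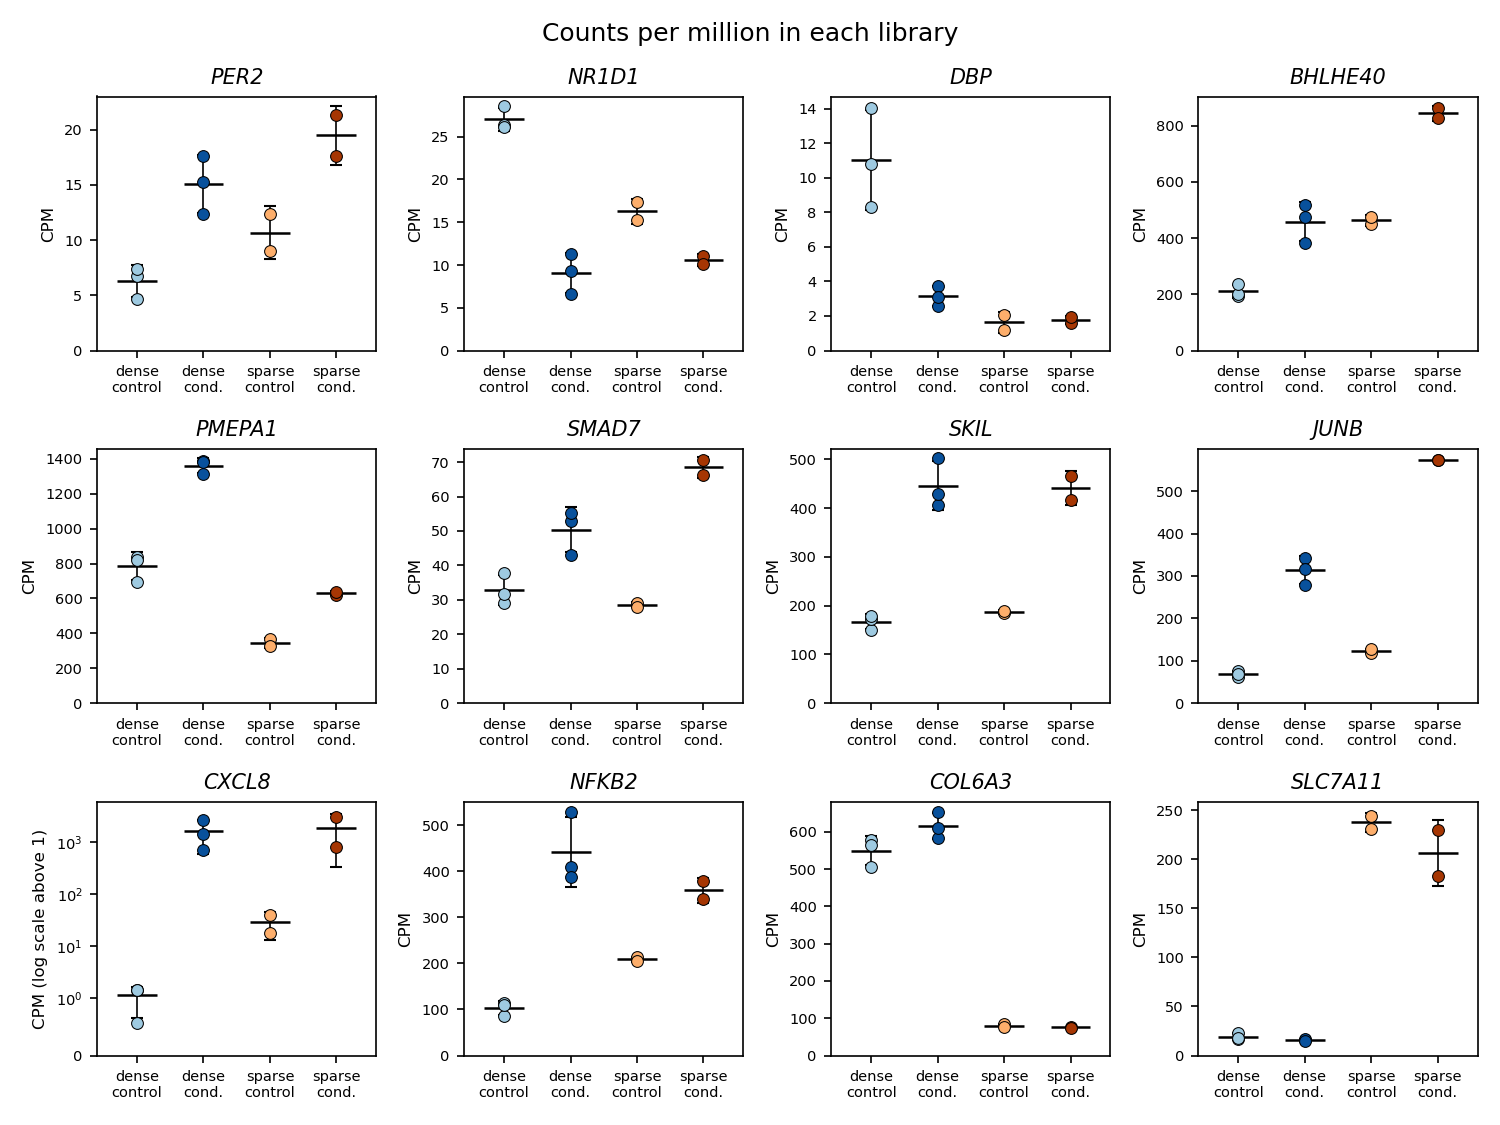
CPM of 12 genes in each library (points), with group means (horizontal lines) and SD (bars), n = 3 in each dense and n = 2 in each sparse group; the CXCL8 axis is logarithmic above 1 CPM. In dense cultures the mean of PER2 went from 6.27 to 15.1 CPM and that of NR1D1 from 27.0 to 9.06 CPM with conditioned medium, while COL6A3 and SLC7A11 separated by density.

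The second comparison asked the same of sparse cultures. TGF-beta targets and immediate early genes rose there too. SMAD7 rose from 28.6 ± 0.799 to 68.5 ± 3.09 CPM (1.26 ± 0.13, adjusted p = 4.7e-05). SKIL rose from 187 ± 3.46 to 441 ± 34.9 CPM (1.24 ± 0.11, adjusted p = 1.12e-05). JUNB rose from 123 ± 5.88 to 574 ± 0.195 CPM (2.22 ± 0.11, adjusted p = 3.43e-08). EGR2 rose from 10.8 ± 2.70 to 53.8 ± 0.893 CPM (2.32 ± 0.15, adjusted p = 5.24e-07). EGR1 rose from 118 ± 32.3 to 377 ± 39.5 CPM (1.68 ± 0.15, adjusted p = 5.3e-05). Of 22 TGF-beta and SMAD target genes, 9 rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 1.38e-07, adjusted p = 0.177 with an estimated correlation). Of 26 immediate early genes, 9 rose and 0 fell (12 and 1, camera adjusted p = 8.04e-09, adjusted p = 0.166 with an estimated correlation), FOS among them (0.77 ± 0.14, adjusted p = 0.00685). Of the 20 clock genes, 2 rose and 0 fell (3 and 2, camera adjusted p = 0.879, median -0.01, mean 0.11): BHLHE40 (0.87 ± 0.13, adjusted p = 0.00131) and its relative BHLHE41 (1.14 ± 0.24, adjusted p = 0.0409). PER2 went from 10.7 ± 2.42 to 19.5 ± 2.65 CPM (0.87 ± 0.22, adjusted p = 0.0624) and NR1D1 from 16.3 ± 1.46 to 10.6 ± 0.699 CPM (-0.62 ± 0.18, adjusted p = 0.0928), both short of the threshold. PER2 passed it without dense conditioned 1 (0.0224), dense conditioned 3 (0.0298), dense control 3 (0.017), by DESeq2's Wald test (0.00149), by limma-voom (0.0491), in a fit of the compared groups alone (0.00428), with the replicate block (0.000629) and without the low-count filter (1.09e-07), in a range of 1.09e-07 to 0.401. NR1D1 passed it without dense conditioned 1 (0.00959), dense conditioned 3 (0.0298), by DESeq2's Wald test (0.0183), in a fit of the compared groups alone (0.00727) and without the low-count filter (0.00021), in a range of 0.00021 to 0.573. DBP (0.12 ± 0.30, adjusted p = 0.936), PER1 (-0.01 ± 0.22, adjusted p = 0.995) and BMAL1 (-0.21 ± 0.19, adjusted p = 0.743) did not pass the test, and neither did CCN2 (-0.56 ± 0.27, adjusted p = 0.469), which passed it in a fit of the compared groups alone (0.0266) and with the replicate block (0.00329) (range 0.00329 to 0.878). Of 9 BMP and ID target genes, 0 rose and 1 fell (0 and 2, camera adjusted p = 0.0976): ID2 (-1.19 ± 0.21, adjusted p = 0.00519). EGR1 lost its call in a fit of the compared groups alone (0.0677), ID2 without sparse conditioned 1 (0.11), and FOS without sparse conditioned 1 (0.0802), sparse control 1 (0.0717) and sparse control 3 (0.0887). BHLHE41 lost it without dense control 2 (0.0608), sparse conditioned 1 (0.209), sparse conditioned 3 (0.0951), sparse control 1 (0.29), sparse control 3 (0.244) and by limma-voom (0.163). Ranges over the alternatives were 5.91e-57 to 0.0677 for EGR1, 2.52e-13 to 0.29 for BHLHE41, 1.7e-09 to 0.11 for ID2 and 1.53e-05 to 0.0887 for FOS.

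Chemokine genes were among the largest rises in sparse cultures. CXCL8 rose from 28.6 ± 15.9 to 1876 ± 1541 CPM (6.04 ± 1.06, adjusted p = 0.0489). CCL2, a monocyte chemokine gene, rose from 4.38 ± 1.16 to 116 ± 73.4 CPM (4.73 ± 0.73, adjusted p = 0.0319). NFKBIA, the NF-kB inhibitor, rose from 45.6 ± 6.34 to 293 ± 78.0 CPM (2.68 ± 0.30, adjusted p = 0.00427). Of 18 NF-kB and cytokine genes, 10 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 2.85 and of 2.76 with CXCL2, at 0 reads in sparse control, at its bound of at least 3.62-fold (camera adjusted p = 2.47e-22, adjusted p = 0.177 with an estimated correlation). LIF rose (1.15 ± 0.14, adjusted p = 0.000505), as did ZC3H12A, an RNase that degrades cytokine mRNAs (3.48 ± 0.26, adjusted p = 0.000298), and LRRC32, a surface anchor of latent TGF-beta (5.09 ± 0.40, adjusted p = 4.47e-06). CLDN4 (1.84 ± 0.16, adjusted p = 1.42e-05), KRT8 (0.42 ± 0.10, adjusted p = 0.0349) and ELF3 (0.607 ± 0.153 CPM against 3 reads in sparse control, adjusted p = 0.0153) were 3 of 10 epithelial markers that rose (5 adjusted over the list alone, camera adjusted p = 0.000982, adjusted p = 0.166 with an estimated correlation). Of 16 cytoskeletal targets of SRF and MRTF, 0 rose and 1 fell (0 and 4), TPM4 (-0.36 ± 0.08, adjusted p = 0.0331, camera adjusted p = 0.0051, adjusted p = 0.677 with an estimated correlation), and this list also lost its call without sparse conditioned 1 (0.0619). The largest falls included CDKN1B, the cell cycle inhibitor p27 (-1.37 ± 0.14, adjusted p = 4.62e-05), CITED2, a transcriptional coregulator (-2.76 ± 0.45, adjusted p = 0.0302), PPP1R3C, a glycogen-targeting phosphatase subunit (-2.21 ± 0.32, adjusted p = 0.00129), and FRAT2 (-1.92 ± 0.28, adjusted p = 0.00179). Ended calls were, with adjusted p in brackets, CXCL8 (0.0909), CCL2 (0.0663), TPM4 (0.0549), KRT8 (0.0567), CITED2 (0.0587) without dense conditioned 2, and CXCL8 (0.0661), CCL2 (0.0528), CITED2 (0.0514) without dense control 1. Further calls that ended were CXCL8 (0.094), CCL2 (0.0673), CITED2 (0.0702) without dense control 2, and CXCL8 (0.097), CCL2 (0.0703), CITED2 (0.0638) without dense control 3. The same holds for CXCL8 (0.156), CCL2 (0.0956), TPM4 (0.0757), KRT8 (0.065), ELF3 (0.121), CITED2 (0.211) without sparse conditioned 1, and TPM4 (0.218), KRT8 (0.25), CITED2 (0.0947) without sparse conditioned 3. Calls also ended for CXCL8 (0.305), CCL2 (0.265), NFKBIA (0.0517), TPM4 (0.501), KRT8 (0.337), ELF3 (0.209), CITED2 (0.112) without sparse control 1, and CXCL8 (0.291), CCL2 (0.234), NFKBIA (0.0617), TPM4 (0.0851), KRT8 (0.185), ELF3 (0.147), CITED2 (0.152) without sparse control 3. To these come CXCL8 (0.0553), CCL2 (0.118), ELF3 (0.262) by limma-voom, and CXCL8 (0.286), CCL2 (0.232) in a fit of the compared groups alone. Others that ended were CXCL8 (0.175), CCL2 (0.137), TPM4 (0.0769), KRT8 (0.0669), CITED2 (0.135) with numbers 1 and 3 alone, and CXCL8 (0.055) without the low-count filter. Ranges were 3.73e-10 to 0.305 for CXCL8, 3.18e-13 to 0.265 for CCL2, 1.49e-15 to 0.0617 for NFKBIA, 0.00698 to 0.501 for TPM4, 0.000926 to 0.337 for KRT8, 2.13e-10 to 0.262 for ELF3 and 2.06e-07 to 0.211 for CITED2.

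For the remaining lists no camera call was made in sparse cultures, with 0 genes rising and 0 falling among 17 G2 and M phase genes (camera adjusted p = 0.865) and 17 S phase genes (camera adjusted p = 0.354). COL1A1 was the 1 of 19 extracellular matrix genes that rose (5 adjusted over the list alone), by 0.45 ± 0.09, adjusted p = 0.014, and its call ended without sparse conditioned 1 (0.0706), sparse conditioned 3 (0.103), sparse control 1 (0.0975) and sparse control 3 (0.161) in a range of 0.000131 to 0.161. In all, edgeR called 518 of 22475 genes in sparse cultures, 348 higher and 170 lower, all of them in the same direction in both pairs, and 129 rose and 42 fell by at least 2-fold. The count was 176 without sparse conditioned 1, 153 without sparse control 1 and 193 without sparse control 3. It was 876 (577 higher, 299 lower) with replicate number as a block, 1002 without the low-count filter, 958 by DESeq2 and 926 in a fit of the compared groups alone. Lists past camera numbered 5, and 9 without sparse control 1. Of the 50 rule-named genes past the threshold, 33 lost their call on leaving out a library. Libraries of the other density matter because all 10 share 1 estimate of the spread.

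Genes called at both densities moved mostly together. Of genes higher in dense cultures, 319 were also higher in sparse cultures, against 38.7 for independent lists, and 145 were lower in both, against 15.1. A single gene was lower in dense and higher in sparse cultures, against 30.8, and 0 were higher in dense and lower in sparse. These comparisons share no library. Across genes the 2 sets of log2 fold changes correlated with r = 0.47 (rho = 0.39) over all 22475 genes and r = 0.82 (rho = 0.83) over the 4488 called in dense cultures, of which 87.8% had the same sign. Over all genes, r was 0.0804 without the low-count filter, 0.77 at a mean of at least 1 CPM, 0.28 without sparse conditioned 1, 0.31 without sparse conditioned 3 and 0.26 without sparse control 3.

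**Figure D3:**
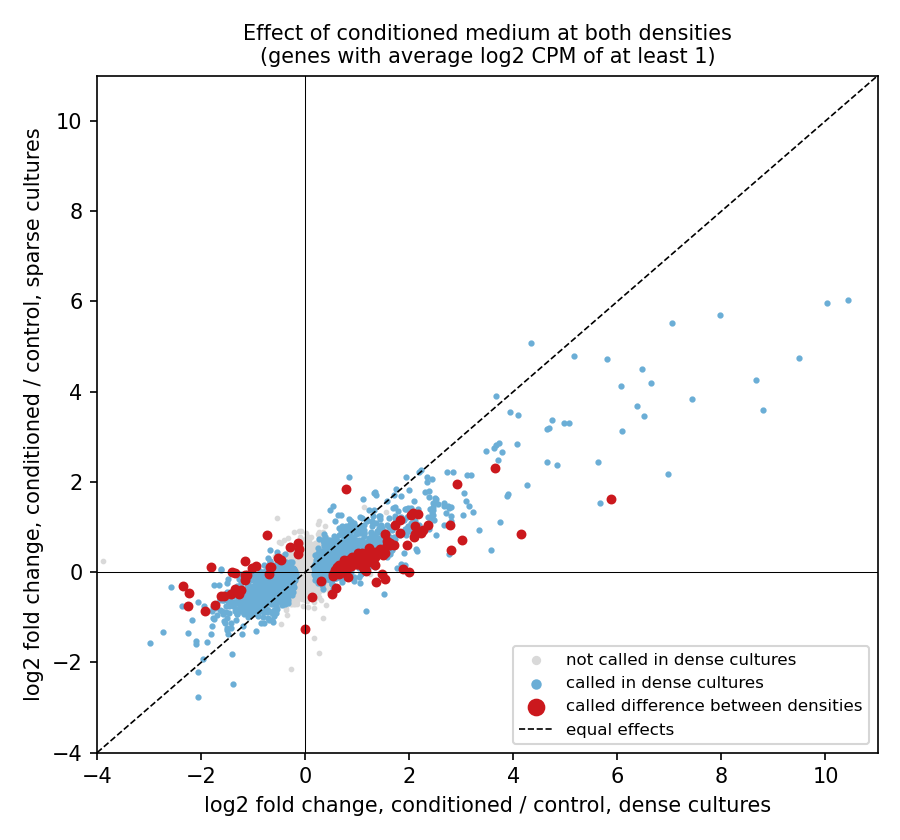
Log2 fold change of conditioned over control medium in dense (x axis) and sparse (y axis) cultures for genes with an average log2 CPM of at least 1, the dashed line marking equal effects. The 131 genes with a called difference between densities (those above the minimum are drawn in red) mostly lie between the horizontal axis and the dashed line.

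The third comparison averaged the medium effect over both densities, weighted equally. PER2 rose (1.06 ± 0.14, adjusted p = 0.000179), and NR1D1 (-1.10 ± 0.12, adjusted p = 1.01e-05) and DBP (-0.85 ± 0.19, adjusted p = 0.00508) fell, DBP only in dense cultures. PER1 (-0.19 ± 0.14, adjusted p = 0.445) and BMAL1 (-0.20 ± 0.12, adjusted p = 0.322) did not pass the test. BMAL1 passed it with the replicate block (0.0447) and without the low-count filter (0.0475), in a range of 0.0447 to 0.613. DBP lost its call in the additive model (0.0856, range 2.61e-09 to 0.0856). Of 20 clock genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.999, median -0.05, mean 0.02). SMAD7 (0.94 ± 0.08, adjusted p = 1.28e-06), SKIL (1.33 ± 0.07, adjusted p = 5.78e-09) and PMEPA1 (0.83 ± 0.06, adjusted p = 1.77e-07) rose. So did JUNB (2.21 ± 0.07, adjusted p = 5.04e-11), EGR1 (1.76 ± 0.10, adjusted p = 1.07e-07), EGR2 (2.99 ± 0.10, adjusted p = 5.04e-11) and FOS (0.57 ± 0.09, adjusted p = 0.000365), while CCN2 did not pass (-0.16 ± 0.18, adjusted p = 0.635). The TGF-beta list held 12 genes that rose and 2 that fell (14 and 3, camera adjusted p = 1.32e-05, adjusted p = 0.273 with an estimated correlation). The immediate early list held 17 and 3 (19 and 3, camera adjusted p = 2.25e-10, adjusted p = 0.13 with an estimated correlation). The NF-kB list held 17 and 0 (18 and 0, camera adjusted p = 6.56e-22, adjusted p = 0.245 with an estimated correlation). Targets of BMP fell in 5 of 9 cases (5, camera adjusted p = 0.0358, adjusted p = 0.671 with an estimated correlation). They were led by ID2 (-1.49 ± 0.13, adjusted p = 1.56e-06), SMAD6 (-0.59 ± 0.10, adjusted p = 0.000819, sparse minus dense effect 1.07) and ID1 (-0.59 ± 0.13, adjusted p = 0.00943). ID1 lost its call without dense control 1 (0.0643, range 1.21e-12 to 0.0643), and the list lost its call with the replicate block (0.0785), without sparse control 1 (0.111), without dense control 2 (0.138) and with numbers 1 and 3 alone (0.186).

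Other lists passed camera for the averaged effect. Of 19 extracellular matrix genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0414, adjusted p = 0.838 with an estimated correlation). Of 17 G2 and M phase genes, 0 rose and 4 fell (0 and 4, camera adjusted p = 0.0135, adjusted p = 0.732 with an estimated correlation). Of 10 heat shock genes, 3 rose and 0 fell (3 and 0, camera adjusted p = 0.00997, adjusted p = 0.732 with an estimated correlation). Of 10 epithelial cell markers, 4 rose and 0 fell (4 and 0, camera adjusted p = 0.0025, adjusted p = 0.13 with an estimated correlation). The matrix list lost its call with the replicate block (0.0715) and without dense conditioned 1 (0.0705), sparse conditioned 1 (0.0548), dense control 1 (0.107), dense conditioned 3 (0.0791), sparse conditioned 3 (0.0714) or sparse control 3 (0.169). The G2 and M list lost it without sparse conditioned 3 (0.0714), and the heat shock list without sparse control 3 (0.0642). In all, edgeR called 3904 genes, 2152 higher and 1752 lower (3496 with the same sign in every pair), and 2461 without sparse control 1. The authors' deposited table gives, for all 10 libraries, 4464 genes past 0.05 of 23015 with an adjusted p, 2532 higher and 1932 lower, and 3799 of the 3904 genes called here are past 0.05 there, in the same direction. In that table PER2 has a log2 fold change of 1.12 (adjusted p = 1.54e-12), NR1D1 -1.19 (2.11e-06), DBP -1.06 (0.0448) and CXCL8 8.87 (4.75e-22).

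The fourth comparison tested whether the medium effect differed with density, as the sparse minus the dense effect. Most genes with a called difference had a smaller effect in sparse cultures. EGR2 rose at both densities and less in sparse cultures (difference -1.34 ± 0.19, adjusted p = 0.0059), and the difference was of the same sign for RELB (-1.74 ± 0.22, adjusted p = 0.00715) and ATF3 (-1.35 ± 0.19, adjusted p = 0.00715). ERRFI1, an inhibitor of the EGF receptor, rose in dense cultures (1.35 ± 0.11, adjusted p = 6.39e-07) and did not pass the test in sparse cultures (-0.21 ± 0.13, adjusted p = 0.562), with a difference of -1.57 ± 0.17, adjusted p = 0.00166. The microRNA host gene MIR222HG differed likewise (-1.70 ± 0.18, adjusted p = 0.00166). SOCS3, a brake on cytokine signalling, went from 44.6 ± 5.84 to 16.9 ± 1.40 CPM in dense and from 21.0 ± 2.04 to 21.0 ± 3.53 CPM in sparse cultures (1.40 ± 0.18, adjusted p = 0.00347). SYBU (1.51 ± 0.21, adjusted p = 0.0059) and DBP (1.93 ± 0.37, adjusted p = 0.031) fell in dense cultures, and CLDN4 rose more in sparse cultures (1.06 ± 0.21, adjusted p = 0.0324). Differences that did not pass the test were PER2 (-0.39 ± 0.28, adjusted p = 0.669), NR1D1 (0.95 ± 0.23, adjusted p = 0.0783), PER1 (0.35 ± 0.28, adjusted p = 0.706) and BMAL1 (-0.03 ± 0.24, adjusted p = 0.982) among clock genes, and SMAD7 (0.64 ± 0.16, adjusted p = 0.101), FOS (0.39 ± 0.18, adjusted p = 0.431), EGR1 (-0.16 ± 0.19, adjusted p = 0.82) and CCN2 (-0.80 ± 0.35, adjusted p = 0.454). NR1D1 passed it without dense conditioned 3 (0.00954), by DESeq2's Wald test (0.00354) and without the low-count filter (4.57e-06) (range 4.57e-06 to 0.309). SMAD7 passed it by DESeq2's Wald test (0.0168), with the replicate block (0.0317) and without the low-count filter (0.000499) (range 0.000499 to 0.338), and CCN2 with the replicate block (0.00613) (range 0.00613 to 0.769). Ended calls were, with adjusted p in brackets, CLDN4 (0.0666) without dense conditioned 2, and DBP (0.0546) without dense control 2. Further calls that ended were DBP (0.0686), CLDN4 (0.123) without sparse conditioned 1, and EGR2 (0.0805), RELB (0.0839), ATF3 (0.0856), DBP (0.216), CLDN4 (0.116) without sparse conditioned 3. The same holds for CLDN4 (0.059) without sparse control 1, and SYBU (0.0506), ATF3 (0.0545), DBP (0.157), CLDN4 (0.189) without sparse control 3. Calls also ended for DBP (0.0753) by limma-voom, and DBP (0.0597), CLDN4 (0.102) with numbers 1 and 3 alone. Ranges were 3.34e-08 to 0.0506 for SYBU, 7.41e-15 to 0.0805 for EGR2, 1.67e-30 to 0.0839 for RELB, 1.86e-18 to 0.0856 for ATF3, 8.49e-11 to 0.216 for DBP and 1.85e-07 to 0.189 for CLDN4.

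NF-kB and cytokine genes had a median difference of -1.44, with 0 positive and 2 negative calls among 18 (0 and 5 adjusted over the list alone, camera adjusted p = 5.52e-10, adjusted p = 0.535 with an estimated correlation). Immediate early genes had one of -0.43, with 0 and 3 of 26 (2 and 10, camera adjusted p = 0.00223, adjusted p = 0.535 with an estimated correlation). Other lists passed camera too, with median differences of -0.26 for SRF and MRTF targets, 0.18 for G2 and M phase genes and -0.34 for heat shock genes. Of 16 SRF and MRTF cytoskeletal target genes, 0 had a positive call and 0 a negative one (0 and 8, camera adjusted p = 0.000251, adjusted p = 0.535 with an estimated correlation). Of 17 G2 and M phase genes, 0 had a positive call and 0 a negative one (3 and 0, camera adjusted p = 0.000302, adjusted p = 0.535 with an estimated correlation). Of 10 heat shock genes, 0 had a positive call and 0 a negative one (0 and 2, camera adjusted p = 0.0304, adjusted p = 0.97 with an estimated correlation). TGF-beta and SMAD targets had a median difference of 0.00 and a mean of -0.03, with 1 and 0 of 22 (2 and 2, camera adjusted p = 0.97). In all, edgeR called 131 genes, 32 positive and 99 negative, each with the same sign in both numbers. The count was 577 without the low-count filter, 495 by DESeq2, 76 with numbers 1 and 3 alone, 78 without sparse conditioned 1, 25 without sparse control 1, 12 without sparse conditioned 3, 16 without sparse control 3, 262 without dense conditioned 3 and 407 (126 positive, 281 negative) with the replicate block.

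The fifth comparison asked what density changed in control medium, as sparse minus dense. Extracellular matrix genes were lower in sparse cultures. COL6A3, a collagen VI chain, fell from 550.0 ± 39.4 to 80.2 ± 4.46 CPM (-2.78 ± 0.09, adjusted p = 1.39e-11). COL5A1 fell from 502 ± 34.2 to 111 ± 1.66 CPM (-2.17 ± 0.09, adjusted p = 8.63e-11). COL1A1, the main collagen of bone, fell from 986 ± 23.1 to 291 ± 11.6 CPM (-1.76 ± 0.09, adjusted p = 6.05e-10). SPARC, a matrix glycoprotein of bone, fell by 1.34 ± 0.07 (adjusted p = 7.84e-10), and COL5A2 by 2.08 ± 0.09 (adjusted p = 9.47e-11). Of 19 matrix genes, 0 rose and 16 fell (0 and 16 adjusted over the list alone, camera adjusted p = 2.56e-09, adjusted p = 0.164 with an estimated correlation). Amino acid stress genes went the other way. SLC7A11, the cystine transporter, rose from 19.4 ± 3.50 to 238 ± 9.69 CPM (3.62 ± 0.13, adjusted p = 5.54e-11). PSAT1, an enzyme of serine synthesis, rose from 22.3 ± 2.46 to 153 ± 1.02 CPM (2.78 ± 0.09, adjusted p = 1.63e-11). TRIB3, a pseudokinase induced by stress, rose from 28.4 ± 3.71 to 168 ± 1.63 CPM (2.56 ± 0.10, adjusted p = 8.35e-11). Of 16 ATF4 and unfolded protein response genes, 12 rose and 0 fell (12 and 1, camera adjusted p = 2.3e-07, adjusted p = 0.164 with an estimated correlation). Interferon-stimulated genes fell in 10 of 14 cases and rose in 0 (10 and 0, camera adjusted p = 0.000103, adjusted p = 0.164 with an estimated correlation). Examples are IFIT2 (-2.16 ± 0.23, adjusted p = 1.61e-06), IFIT1 (-1.69 ± 0.17, adjusted p = 1.13e-06) and IFI6 (-1.20 ± 0.11, adjusted p = 2.63e-07). In GRCh38, COL6A3 lies at ENSG00000163359, chromosome 2, 237324003 to 237414375, and SLC7A11 at ENSG00000151012, chromosome 4, 138164097 to 138242349.

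Immediate early genes were higher in sparse cultures, 20 of 26 with 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 1.82e-06, adjusted p = 0.164 with an estimated correlation). ATF3 rose from 9.02 ± 0.992 to 85.8 ± 2.29 CPM (3.25 ± 0.14, adjusted p = 4.66e-10). NR4A1, an orphan nuclear receptor, rose from 18.1 ± 4.44 to 64.8 ± 2.93 CPM (1.84 ± 0.15, adjusted p = 4.22e-07). DUSP1, a MAP kinase phosphatase, rose from 36.6 ± 3.79 to 110.5 ± 11.6 CPM (1.60 ± 0.13, adjusted p = 4.27e-07). EGR1 rose (1.28 ± 0.14, adjusted p = 5.63e-06), and FOS did not pass the test (0.27 ± 0.13, adjusted p = 0.105) but did without dense control 2 (0.0322), with numbers 1 and 3 alone (0.0365) and with the replicate block (0.0208) (range 0.0208 to 0.309). Proliferation genes were higher: 12 of 17 G2 and M phase genes rose and 1 fell (12 and 1, camera adjusted p = 0.00594, adjusted p = 0.435 with an estimated correlation). Among the risen were TPX2 (0.54 ± 0.08, adjusted p = 5.02e-05), HMMR (0.46 ± 0.08, adjusted p = 0.000332) and BUB1 (0.40 ± 0.08, adjusted p = 0.000465). Of 17 S phase genes, 11 rose and 0 fell (11 and 0, camera adjusted p = 0.00118, adjusted p = 0.567 with an estimated correlation). CDC6 (0.86 ± 0.09, adjusted p = 2.71e-06), MCM7 (0.55 ± 0.09, adjusted p = 0.000121) and RRM2 (0.59 ± 0.09, adjusted p = 9.8e-05) rose. Histone genes fell in 6 of 9 cases, 0 rising (0 and 6, camera adjusted p = 0.00594, adjusted p = 0.316 with an estimated correlation). They include H1-2 (-1.66 ± 0.09, adjusted p = 1.1e-09), H4C8 (-2.11 ± 0.21, adjusted p = 1.81e-06) and H2BC5 (-1.42 ± 0.15, adjusted p = 1.42e-06). Reads shared between histone copies and poly(A) selection leave them uncertain. Of 17 hypoxia and glycolysis genes, 10 rose and 1 fell (10 and 1, camera adjusted p = 0.000599, adjusted p = 0.156 with an estimated correlation). HK2 (2.57 ± 0.10, adjusted p = 3.88e-11), ENO1 (0.69 ± 0.07, adjusted p = 5.61e-07) and VEGFA (1.51 ± 0.13, adjusted p = 3.12e-07) rose. Of 13 p53 targets, 8 rose and 1 fell (8 and 1, camera adjusted p = 0.00565, adjusted p = 0.269 with an estimated correlation). GDF15 (3.55 ± 0.19, adjusted p = 5.73e-08), CDKN1A (1.09 ± 0.10, adjusted p = 5.26e-07) and MDM2 (0.79 ± 0.08, adjusted p = 1.53e-06) rose. Targets of YAP and TAZ, which respond to cell contact, rose in 10 of 20 cases and fell in 4 (11 and 4, camera adjusted p = 0.0213, adjusted p = 0.435 with an estimated correlation). Among them CCN1 (2.05 ± 0.12, adjusted p = 1.73e-08), GADD45A (1.76 ± 0.12, adjusted p = 1.82e-08) and CCN2 (1.48 ± 0.24, adjusted p = 0.00178) were higher. The list lost its call without dense control 1 (0.0927).

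Clock genes differed with density in control medium, 5 of 20 higher and 8 lower (5 and 9 adjusted over the list alone, camera adjusted p = 0.254). DBP fell from 11.1 ± 2.89 to 1.63 ± 0.632 CPM (-2.77 ± 0.27, adjusted p = 1.27e-06). BHLHE41 fell from 29.3 ± 6.89 to 6.32 ± 0.151 CPM (-2.21 ± 0.23, adjusted p = 2.29e-05). NR1D1 fell from 27.0 ± 1.37 to 16.3 ± 1.46 CPM (-0.73 ± 0.16, adjusted p = 0.0018). BHLHE40 (1.14 ± 0.11, adjusted p = 1.2e-06) and PER2 (0.76 ± 0.20, adjusted p = 0.00819) rose, and PER1 (-0.70 ± 0.20, adjusted p = 0.0179) and BMAL1 (-0.48 ± 0.17, adjusted p = 0.0427) fell. TGF-beta and SMAD targets split, 8 of 22 higher and 9 lower (8 and 9, camera adjusted p = 0.552). COL4A1 (-1.65 ± 0.09, adjusted p = 7.57e-10) and LTBP3 (-1.58 ± 0.11, adjusted p = 3.12e-08) fell, and SMAD7 did not pass the test (-0.20 ± 0.12, adjusted p = 0.191). Of 20 family ligands, receptors and SMADs, 6 rose and 9 fell (6 and 10, camera adjusted p = 0.409, median -0.21, mean 0.04), TGFBR2, a TGF-beta receptor, among the latter (-0.80 ± 0.10, adjusted p = 1.11e-05). NF-kB and cytokine genes were higher in 8 of 18 cases and lower in 0 (8 and 0, camera adjusted p = 0.00804, adjusted p = 0.692 with an estimated correlation). CXCL8 rose from 1.13 ± 0.479 to 28.6 ± 15.9 CPM (4.65 ± 0.99, adjusted p = 0.00962). RELB (1.19 ± 0.16, adjusted p = 6.76e-05), NFKB2 (1.01 ± 0.13, adjusted p = 4.14e-05) and LIF (0.88 ± 0.13, adjusted p = 7.01e-05) rose as well. Ended calls were, with adjusted p in brackets, BMAL1 (0.058) without dense conditioned 2, and PER1 (0.0679) without dense control 1. Further calls that ended were BMAL1 (0.0902) without dense control 2, and BMAL1 (0.132) without dense control 3. The same holds for BMAL1 (0.0572) without sparse conditioned 1, and BMAL1 (0.0541) without sparse conditioned 3. Calls also ended for CXCL8 (0.0522), PER1 (0.105), PER2 (0.12), BMAL1 (0.274) without sparse control 1, and PER1 (0.0815), BMAL1 (0.0735) without sparse control 3. To these come CXCL8 (0.145), BMAL1 (0.054) by limma-voom, and CXCL8 (0.0614), BMAL1 (0.121) with numbers 1 and 3 alone. Ranges were 2.15e-08 to 0.145 for CXCL8, 1.19e-07 to 0.105 for PER1, 1.52e-07 to 0.12 for PER2 and 2.16e-05 to 0.274 for BMAL1.

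The largest density effects included MMP3, a matrix metalloproteinase (5.50 ± 0.30, adjusted p = 5.57e-08), the hair keratin KRT34 (4.60 ± 0.26, adjusted p = 1.59e-08) and SPX, the gene of the peptide spexin (4.34 ± 0.18, adjusted p = 5.66e-10), all higher in sparse cultures. MMP7, another metalloproteinase (-5.32 ± 0.64, adjusted p = 0.000448), CHI3L1 (-5.10 ± 0.43, adjusted p = 2.81e-07) and F13A1, a clotting factor subunit (-5.46 ± 0.33, adjusted p = 4.28e-09), were lower. Epithelial markers went both ways, 4 of 10 higher and 3 lower (4 and 3, camera adjusted p = 0.834): ESRP1, a splicing factor (4.60 ± 0.36, adjusted p = 2.54e-07), and CDH1, E-cadherin (3.43 ± 0.30, adjusted p = 2.08e-07), rose, and KRT14 fell (-4.12 ± 0.46, adjusted p = 3.3e-06). PHLDA1 fell (-3.40 ± 0.20, adjusted p = 9.25e-08) although 7 of 13 ERK feedback genes rose and 1 fell (7 and 1, camera adjusted p = 0.151). In all, edgeR called 9510 of 22475 genes for density in control medium, 4660 higher and 4850 lower, of which 1057 rose and 1873 fell by at least 2-fold, and 9501 had the same sign in both pairs.

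**Figure D4:**
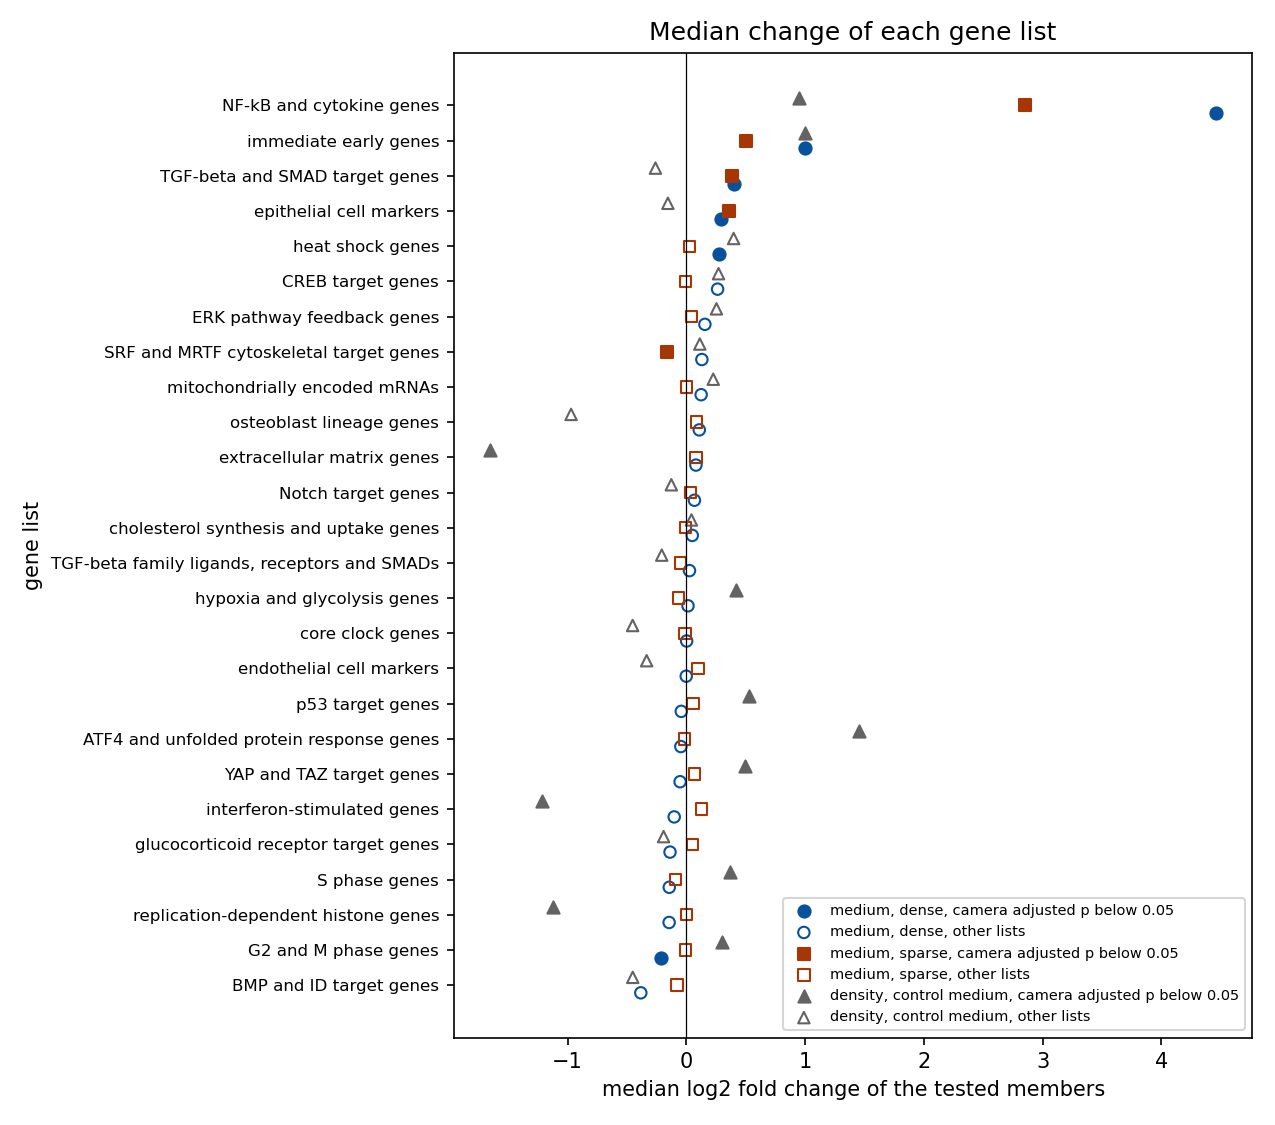
Median log2 fold change of the tested members of 26 gene lists, for the medium effect in dense (circles) and sparse (squares) cultures and the density effect in control medium (triangles), filled where camera's adjusted p with a preset correlation passed 0.05. Extracellular matrix genes lie at -1.65 for density.

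The sixth comparison asked the same of density in conditioned medium. Matrix genes were again lower in sparse cultures, 18 of 19 with 0 higher (18 and 0 adjusted over the list alone, camera adjusted p = 9.35e-13, adjusted p = 0.185 with an estimated correlation), COL3A1 (-3.74 ± 0.17, adjusted p = 2.81e-10) and COL6A3 (-3.03 ± 0.09, adjusted p = 8.4e-12) among them. Of 14 interferon-stimulated genes, 11 fell and 0 rose (11 and 0, camera adjusted p = 8.55e-05, adjusted p = 0.207 with an estimated correlation). Examples are IFIT2 (-2.68 ± 0.24, adjusted p = 4.6e-07) and IFI44 (-2.33 ± 0.24, adjusted p = 2.26e-06). SLC7A11 (3.69 ± 0.13, adjusted p = 7.42e-11), TRIB3 (3.24 ± 0.11, adjusted p = 1.99e-11), PSAT1 (2.86 ± 0.09, adjusted p = 1.99e-11) and GDF15 (4.31 ± 0.19, adjusted p = 2.31e-08) rose, and 13 of 16 ATF4 and unfolded protein response genes rose with 1 falling (13 and 3, camera adjusted p = 1.43e-07, adjusted p = 0.185 with an estimated correlation). In the G2 and M list 16 of 17 rose, 0 falling (16 and 0, camera adjusted p = 1.38e-06, adjusted p = 0.234 with an estimated correlation), TPX2 among them (0.72 ± 0.08, adjusted p = 4.16e-06). CXCL10, a target of interferon and NF-kB signalling, was lower (0.613 ± 0.482 against 13.8 ± 8.03 CPM, -4.51 ± 0.68, adjusted p = 0.00135), and of 18 NF-kB and cytokine genes 0 rose and 3 fell (0 and 0, camera adjusted p = 0.184). Clock genes rose in 3 of 20 cases and fell in 6 (3 and 6, camera adjusted p = 0.524), with BHLHE41 (-2.26 ± 0.22, adjusted p = 2.07e-05), NPAS2 (-1.37 ± 0.15, adjusted p = 3.47e-06), DBP (-0.84 ± 0.27, adjusted p = 0.0229) and BMAL1 (-0.51 ± 0.17, adjusted p = 0.0399) lower. PER2 (0.37 ± 0.20, adjusted p = 0.169), NR1D1 (0.22 ± 0.16, adjusted p = 0.33) and PER1 (-0.35 ± 0.20, adjusted p = 0.215) did not pass the test. SMAD7 (0.44 ± 0.11, adjusted p = 0.00627), EGR1 (1.11 ± 0.13, adjusted p = 2.39e-05) and FOS (0.67 ± 0.13, adjusted p = 0.000624) rose, PMEPA1 fell (-1.11 ± 0.09, adjusted p = 1.06e-07), and CCN2 did not pass (0.68 ± 0.25, adjusted p = 0.0684). PER2 passed it with the replicate block (0.00527) and without the low-count filter (0.0208) (range 0.00527 to 0.552), and PER1 without dense conditioned 1 (0.0459) and without the low-count filter (0.0144) (range 0.0144 to 0.716). Calls were also gained by NR1D1 without dense conditioned 3 (0.0366) (range 0.0366 to 0.85) and CCN2 without dense conditioned 3 (0.000743), by DESeq2's Wald test (0.038), with the replicate block (0.00017) and with the stricter filter (0.0437) (range 0.00017 to 0.291). Ended calls were, with adjusted p in brackets, BMAL1 (0.0829), DBP (0.077) without dense conditioned 2, and BMAL1 (0.119) without dense conditioned 3. Further calls that ended were BMAL1 (0.0633) without dense control 2, and SMAD7 (0.0552), BMAL1 (0.266), DBP (0.181) without sparse conditioned 1. The same holds for BMAL1 (0.0771), DBP (0.0607) without sparse conditioned 3, and BMAL1 (0.0546) without sparse control 1. Calls also ended for BMAL1 (0.0551) without sparse control 3, and BMAL1 (0.0603), DBP (0.0729) by limma-voom. To these come BMAL1 (0.126), DBP (0.0966) with numbers 1 and 3 alone. Ranges were 8.04e-05 to 0.0552 for SMAD7, 1.92e-05 to 0.266 for BMAL1 and 6.57e-05 to 0.181 for DBP.

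Further lists passed camera for density in conditioned medium. Of 26 immediate early genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000598, adjusted p = 0.242 with an estimated correlation). Of 17 S phase genes, 14 rose and 0 fell (14 and 0, camera adjusted p = 4e-05, adjusted p = 0.504 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 11 rose and 1 fell (11 and 1, camera adjusted p = 0.000923, adjusted p = 0.185 with an estimated correlation). Of 13 p53 target genes, 7 rose and 1 fell (7 and 1, camera adjusted p = 0.00265, adjusted p = 0.234 with an estimated correlation). Of 20 YAP and TAZ target genes, 9 rose and 2 fell (10 and 3, camera adjusted p = 0.00687, adjusted p = 0.393 with an estimated correlation). Of 9 replication-dependent histone genes, 0 rose and 5 fell (0 and 5, camera adjusted p = 0.00222, adjusted p = 0.237 with an estimated correlation). In all, edgeR called 7969 genes for density in conditioned medium, 3770 higher and 4199 lower, and 7966 had the same sign in both pairs. Of genes higher in sparse cultures in control medium, 3060 were also higher in conditioned medium, against 782 for independent lists, and 3399 were lower in both, against 906. Opposite calls numbered 26 and 6. These comparisons share no library, and across genes their log2 fold changes correlated with r = 0.74 (rho = 0.72), or r = 0.88 (rho = 0.91) over the 9510 genes called in control medium, of which 95.7% had the same sign.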

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

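All tests that weigh explanations in this part were chosen only after the result was seen, while the test of the difference itself was planned. What stood out is that the response to conditioned medium differed between dense and sparse cultures for 131 genes, by a direct test of the sparse minus the dense effect. Positive calls of named genes included DBP 1.93 (adjusted p = 0.031), HOXA5 1.77 (0.023), SYBU 1.51 (0.0059), SOCS3 1.40 (0.00347), CDKN1C 1.12 (0.0124), SMAD6 1.07 (0.031), CLDN4 1.06 (0.0324). Negative ones included NFKB2 -1.31 (adjusted p = 0.0101), EGR2 -1.34 (0.0059), ATF3 -1.35 (0.00715), ERRFI1 -1.57 (0.00166), MIR222HG -1.70 (0.00166), RELB -1.74 (0.00715), LUCAT1 -1.81 (0.00806), IL7R -2.31 (0.00728), ROBO4 -3.31 (0.0124), TNFRSF9 -4.26 (0.0498). Calls ended without dense conditioned 1 for SMAD6 (0.0616), and without dense conditioned 2 for SMAD6 (0.0646), CLDN4 (0.0666), TNFRSF9 (0.0679). They also ended without dense control 1 for IL7R (0.0742), ROBO4 (0.0838), TNFRSF9 (0.0972), and without dense control 2 for DBP (0.0546), SMAD6 (0.0643), ROBO4 (0.0545), TNFRSF9 (0.105). Further calls ended without dense control 3 for ROBO4 (0.0601), TNFRSF9 (0.126), and without sparse conditioned 1 for DBP (0.0686), CDKN1C (0.0516), CLDN4 (0.123), TNFRSF9 (0.0603). More ended without sparse conditioned 3 for DBP (0.216), HOXA5 (0.182), CDKN1C (0.0825), SMAD6 (0.235), CLDN4 (0.116), NFKB2 (0.114), EGR2 (0.0805), ATF3 (0.0856), RELB (0.0839), LUCAT1 (0.1), ROBO4 (0.081), TNFRSF9 (0.161), and without sparse control 1 for HOXA5 (0.133), SMAD6 (0.111), CLDN4 (0.059), NFKB2 (0.0698), IL7R (0.0575), ROBO4 (0.101), TNFRSF9 (0.235). Others ended without sparse control 3 for DBP (0.157), HOXA5 (0.0919), SYBU (0.0506), CDKN1C (0.0904), SMAD6 (0.171), CLDN4 (0.189), NFKB2 (0.0757), ATF3 (0.0545), LUCAT1 (0.0506), IL7R (0.0723), ROBO4 (0.0864), TNFRSF9 (0.2), and by limma-voom for DBP (0.0753), ROBO4 (0.0675), TNFRSF9 (0.0946). Others ended with RLE scaling for TNFRSF9 (0.0502), and with numbers 1 and 3 alone for DBP (0.0597), HOXA5 (0.081), SMAD6 (0.133), CLDN4 (0.102), TNFRSF9 (0.166). Others ended with the replicate block for TNFRSF9 (0.0575). Ranges over the alternatives were 8.49e-11 to 0.216 for DBP, 4.84e-06 to 0.182 for HOXA5, 3.34e-08 to 0.0506 for SYBU, 1.96e-08 to 0.0904 for CDKN1C, 5.04e-06 to 0.235 for SMAD6, 1.85e-07 to 0.189 for CLDN4, 5.25e-21 to 0.114 for NFKB2, 7.41e-15 to 0.0805 for EGR2, 1.86e-18 to 0.0856 for ATF3, 1.67e-30 to 0.0839 for RELB, 9.52e-14 to 0.1 for LUCAT1, 5.84e-29 to 0.0742 for IL7R, 8.23e-19 to 0.101 for ROBO4 and 4.28e-09 to 0.235 for TNFRSF9.

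The response in sparse cultures was about 0.502 times that in dense cultures over 12241 genes. If the medium of 1 replicate number had been more potent, the ratio of the sparse to the dense response within a number, each set against a dense pair of another number, would lie much closer to 1, but the highest of 4 was 0.518 (this assumes that libraries of a number shared a medium preparation, which the labels do not state). A single scale factor for every gene stays open, since the ranges resample genes, not libraries. TGF-beta and SMAD targets had a ratio of 0.781 (0.597 to 0.916), and NF-kB and cytokine genes 0.608 (0.549 to 0.675). Another level in sparse control medium stays open, because a median of 102% (quartiles 52.4% and 154%) of the difference over the 131 genes lies in control medium, where the median density effect was 0.90 for the 99 genes with a negative difference and -1.05 for the 32 with a positive one. A biological effect of density may underlie it.

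Of 18 NF-kB and cytokine genes, 8 were higher in sparse than in dense control cultures and 0 lower, and the call of the list (camera adjusted p = 0.00804) was lost with an estimated correlation (adjusted p = 0.692), while fry, which sets no list against other genes, gave 0.075. Reads carried over from conditioned libraries would raise all members by about the same share of their sparse conditioned level, but the rise over dense control was 1.47% of it for CXCL8, a median of 5.62% for the 17 others and 7.15% to 29.3% for the 7 others that passed the test, while 4 that did not pass lay below CXCL8. For CXCL8 (1.53% of its conditioned level), dense cultures argue against equal carry-over (control up to 1.41, conditioned from 691 CPM). Unequal carry-over is open. Both sparse control libraries exceeded all 3 dense ones in 13 of 18 members (chance gives 10%). Members correlate (0.768), so this only weakly argues against 1 unusual library. A biological effect of plating density may be the source and was not tested apart from these.

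The NF-kB and cytokine response differed with replicate number, with median log2 responses of 5.06, 3.63 and 3.59 in dense numbers 1, 2 and 3 and of 3.18 and 2.16 in sparse numbers 1 and 3. Depth is open, as some members had few reads. Scaling would move TGF-beta and SMAD targets as much, but their span was 0.201 of that of NF-kB and cytokine genes. A scale factor per number on every gene is open. The ratio of number 1 to number 3 was 1.41 in dense and 1.47 in sparse cultures for these genes and 1.70 and 1.62 for slopes over all genes. The 1.01 of TGF-beta and SMAD targets in sparse cultures (95% range over resampled genes -0.105 to 1.80) cannot be told apart from 1.62. No biological explanation was tested.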

How the results depend on the processing

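The alternatives with numbers 1 and 3 alone and the additive model, and the ratios within numbers, were chosen after seeing the data, and the others were planned. Calls for density in control medium, 4660 higher and 4850 lower, turned to more higher than lower with RLE scaling (4827 and 4726), by DESeq2 (4872 and 4808), by limma-voom (4776 and 4773), without dense conditioned 3 (4723 and 4705) and without sparse control 1 (3476 and 3454). Of 456 named gene results in 8608 settings, 8018 kept their direction and side of the threshold, 552 lost the call, 38 gained one and 0 reversed, and 130 results changed at least once. Outside leaving out a library, 3895 of 4048 settings kept both. Genes called in sparse cultures numbered 518, and 1002 without the low-count filter, 958 by DESeq2, 876 with the replicate block and 926 in a fit of the compared groups alone. Called differences numbered 131, and 577 without the filter, 495 by DESeq2, 407 with the block and 76 with numbers 1 and 3. In dense cultures 4488 became 2825 with numbers 1 and 3 and 5297 (2886 higher, 2411 lower) with the block. Leaving out 1 library in turn gave 3182 to 4418 in dense cultures, 153 to 749 in sparse, 2461 to 3927 averaged, 12 to 262 for the difference, and 6930 to 9615 and 5800 to 8870 for density in control and conditioned medium. Fewer libraries leave less power, and otherwise the cause was not tested.

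With an estimated correlation 0 lists passed in dense, sparse and averaged comparisons and for density in control medium, against 6, 5, 8 and 11 (the cause was not tested). By fry, which sets no list against other genes, 19 passed for density in control medium. Lists past camera but not fry were, for the difference of medium effects, NF-kB, immediate early, G2 and M and SRF and MRTF genes (0.188 each) and heat shock genes (0.61). Others were SRF and MRTF targets in sparse cultures (0.248), matrix (0.159), G2 and M (0.0519) and heat shock genes (0.0519) averaged, and NF-kB genes for density in control medium (0.075). Leaving out 1 library gave 6 to 8, 4 to 9, 6 to 9 and 10 to 12 lists. The correlation of dense and sparse effects (0.47) was 0.0804 without the filter, 0.77 at a mean of 1 CPM, 0.44 with numbers 1 and 3 and 0.26 to 0.47 on leaving out 1 library. The replicate block also ended the calls of TXNIP in sparse cultures (0.109), SLITRK6 averaged (0.0714), and RELB (0.0577) and PECAM1 (0.0867) for density in conditioned medium, and beyond these and values given beside results it changed no other call among named genes. Depth limits genes near the floor, and few libraries limit small changes, of which simulated data recovered 11% for a difference of 0.5 in genes at a mean of at least 1 CPM.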

Other observations

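Gene families and their tests were chosen after seeing the data, while the splits at the end were planned. For density in control medium, sparse minus dense, of 20 aminoacyl-tRNA synthetase genes, 19 rose and 1 fell (median 1.14, camera adjusted p = 3.89e-12, 0.0762 with an estimated correlation). Of 10 serine and one-carbon pathway genes, 9 rose and 0 fell (median 1.44, camera adjusted p = 9.96e-08, 0.0776 with an estimated correlation). Of 8 solute carrier genes of amino acid transport, 6 rose and 0 fell (camera adjusted p = 1.77e-05, 0.0776 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes, 43 rose and 0 fell (median 0.27, camera adjusted p = 1.55e-08, 0.35 with an estimated correlation). Of 81 ribosomal protein genes, 16 rose and 0 fell (median 0.09, camera adjusted p = 0.0111, 0.752 with an estimated correlation). Of 37 proteasome subunit genes, 23 rose and 3 fell (median 0.31, camera adjusted p = 1.62e-05, 0.416 with an estimated correlation). Of 52 clustered protocadherin genes, 0 rose and 31 fell (median -1.02, camera adjusted p = 7.6e-13, 0.0762 with an estimated correlation). Of 12 FOXO target genes, 0 rose and 9 fell (median -1.07, camera adjusted p = 8.12e-05, 0.13 with an estimated correlation). No call was made for chemokine (3 rose and 7 fell, camera adjusted p = 0.491), ZNF-named zinc finger (84 rose and 74 fell, 0.878), HOX (6 rose and 15 fell, 0.127), TNF and TNF receptor family (5 rose and 6 fell, 0.306) and tubulin (7 rose and 3 fell, 0.253) genes. For density in conditioned medium the 8 families with a call in control medium had one again (at least 0.0626 with an estimated correlation), as did chemokine (1 higher, 10 lower, camera adjusted p = 0.00179, 0.454 with an estimated correlation) and TNF family genes (2 higher, 8 lower, 0.0363 and 0.25). Protocadherin and zinc finger genes have paralogs that share reads.

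With conditioned medium in dense cultures, of 36 HOX genes, 0 rose and 20 fell (median -0.66, camera adjusted p = 2.66e-09, 0.251 with an estimated correlation). Of 438 zinc finger protein genes named ZNF, 38 rose and 144 fell (median -0.23, camera adjusted p = 1.43e-06, 0.103 with an estimated correlation). Of 12 FOXO target genes, 2 rose and 8 fell (median -0.57, camera adjusted p = 0.00117, 0.251 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes, 9 rose and 1 fell (median 0.18, camera adjusted p = 0.000602, 0.251 with an estimated correlation). Of 37 proteasome subunit genes, 9 rose and 0 fell (median 0.11, camera adjusted p = 5.9e-05, 0.433 with an estimated correlation). Of 52 clustered protocadherin genes, 0 rose and 2 fell (median -0.13, camera adjusted p = 0.0185, 0.433 with an estimated correlation). Of 20 chemokine genes, 11 rose and 1 fell (camera adjusted p = 3.03e-07, 0.251 with an estimated correlation). Of the 13 families tried, the others did not pass camera in dense cultures: serine and one-carbon pathway (adjusted p = 0.73), ribosomal protein (0.605), mitochondrial ribosomal protein (0.212), TNF and TNF receptor family (0.0617), amino acid transport (0.516) and tubulin genes (0.126). In sparse cultures, of 36 HOX genes, 0 rose and 3 fell (median -0.34, camera adjusted p = 3.83e-05, 0.508 with an estimated correlation). Of 438 zinc finger protein genes named ZNF, 5 rose and 24 fell (camera adjusted p = 7.27e-09, 0.0414 with an estimated correlation). Of 20 chemokine genes, 3 rose and 0 fell (camera adjusted p = 1.91e-05, 0.508 with an estimated correlation). Of 22 TNF and TNF receptor family genes, 2 rose and 0 fell (median 0.24, camera adjusted p = 0.0285, 0.386 with an estimated correlation). No call was made there for FOXO targets, with 1 rising and 1 falling (camera adjusted p = 0.311), or, with 0 and 0, for aminoacyl-tRNA synthetase (0.943), serine and one-carbon pathway (0.402), ribosomal protein (0.943), mitochondrial ribosomal protein (0.314), proteasome subunit (0.831), clustered protocadherin (0.943), amino acid transport (0.943) and tubulin (0.215) genes.

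Other splits of the libraries were fitted in the same way. For the medium effect in dense cultures, the 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, and 1 split, the real one, called 4488 genes while the highest of the others called 0. For the averaged effect, only the real one of 60 splits within density called 3904 genes. The highest of the others called 755, but numbers pair dense libraries, so this cannot exclude chance. The 16 splits that part every same-numbered pair are too few for a share under 0.05, the highest of the others there called 338, and the remaining splits put both libraries of some number on 1 side.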
